A study of Mus musculus with 9 samples.

How the data were processed

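RNA was measured by bulk RNA sequencing in 9 libraries of CD45+ cells, the leukocytes of the tissue, sorted by flow cytometry from homogenised mouse placenta at embryonic day 17. Per the labels' protocols, cDNA was made and amplified with Clontech reagents, libraries were prepared with Nextera XT, and sequencing was paired-end. This kit does not mark strand, so reads of overlapping sense and antisense genes cannot be told apart.

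The authors deposited 1 table per library, in TPM to 1 decimal, with 35869 features named by gene symbol. Per the submitters' processing notes, the tools were Trim Galore 0.4.2, cutadapt 1.9.1, STAR 2.6.1e and featureCounts 1.6.2 with the mm10 build, and the annotation behind the symbols is not given in the sources used here. TPM divides a gene's reads by its length and scales each library to the same total, so it keeps no library total, and a gene that takes a larger share lowers all others. Multiplying the values of 1304 short RNA loci by their length gave whole multiples of 1 step per library for 1536 of 1536 low values, within a tolerance of 0.15 steps, and that step gave the relative depth. One TPM corresponded to 7.93 to 13.25 reads per kb of transcript. With gene lengths from GENCODE M21, this is roughly 22400000 to 37200000 assigned reads per library, an approximation because the authors' gene lengths are not known. Loci of small RNAs held 12.9% to 13.8% of each library's TPM, since division by a short length inflates them. Coordinates are from the RefSeq table of assembly GRCm38.p6, the same coordinates as mm10, and 32401 of the 35869 symbols matched it.

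Libraries were grouped by their titles, in 3 groups of 3: Ctrl (wild type, normal pregnancy), WT_STZ (wild type, diabetic pregnancy) and Nlrp3KO_STZ (lacking Nlrp3, diabetic pregnancy). The treatment labels give the same groups, while the label for disease state names a diabetic pregnancy for the Ctrl libraries too. Nothing in the labels says that replicates came from separate litters, so p-values measure the spread between these samples, which may in part be technical. No group lacked Nlrp3 in a normal pregnancy. The comparison of Nlrp3KO_STZ with Ctrl therefore changes genotype and diabetes together, and no interaction could be tested.

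Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a mean per group, all 9 libraries in 1 fit (6 residual degrees of freedom) and an intensity trend in the variance. Genes entered at 1 TPM or more in at least 3 libraries, which left 14160, and p-values were adjusted by the Benjamini-Hochberg method at 0.05 within each comparison. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Levels are means ± SD of TPM over 3 libraries, and log2 fold changes carry the standard error of the fit. Single values were compared by an exact two-sided permutation test, which cannot go below 0.1 with 3 libraries against 3. Gene lists of 18 pathways and 15 cell types, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, with at least 5 tested members, adjusted over 33 lists per comparison. Each was also tested with an estimated correlation and with fry, which asks whether a list's genes move one way on balance and does not set the list against other genes. Of 793 list members, sex-linked and strain-linked genes included, 783 were found in the files. Nlrp3 itself was in no list. Some lists share members, so their results are not independent. Among these, S100a8 and S100a9 are in the AGE-RAGE and neutrophil lists and Il1b is in the inflammasome and cytokine lists. Gata2 is in the mast cell, basophil and eosinophil list and in the stem and progenitor list.

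Genes were named by a rule fixed at the same time as the lists. It took Nlrp3, then the 8 largest rises and the 8 largest falls among genes with adjusted p below 0.05, a mean of at least 5 TPM in the higher group and no overlap between the libraries, then up to 4 members with the smallest p of each list described. Predicted genes and small RNAs were counted but not described. Genes chosen after their values were seen are said to be so.

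The gene test was tested on simulated data drawn from the 14160 genes' own means and spreads for WT_STZ vs Ctrl. In each of 10 sets 200 genes were changed, taken only from those with a mean log2(TPM + 1) above that of 5 TPM. The test recovered 12.1% of changes of 0.5 in log2, 74.8% of changes of 1 and 95.9% of changes of 2, and 5.81% of calls were false. The recovered shares do not cover changes in genes at lower levels. A simulated shift of 0.3 in 1 list was found in 10 of 10 sets by each of the 3 list tests. Of 320 unchanged lists, camera at the preset correlation called 5, camera with an estimated correlation 0 and fry 3. The simulated genes were independent, which real list members are not.

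Alternatives were other pseudocounts (0.1 and 5), other filters on low values, median-of-ratios and quantile scaling, TPM rescaled without erythroid and mitochondrial genes, fits on 6 libraries, fits without the trend, library weights, the replicate number as a block, and each library left out in turn. TPM rescaled without small RNA loci was added after seeing the data. Correlations between comparisons that share libraries were set beside 100 simulations of unchanged groups. Bootstrap intervals are 95% intervals from 10000 draws over genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were also used.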

Results

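Leukocytes (CD45+ cells) from placentas at embryonic day 17 were profiled to ask what maternal diabetes changes in their transcripts and what changes with it when Nlrp3 is lacking. NLRP3 is the sensor of an inflammasome, a complex that activates caspase-1 and releases interleukin-1β. Streptozotocin (STZ), a toxin of pancreatic beta cells, is named in the group names of the diabetic pregnancies. There were 3 Ctrl, 3 WT_STZ and 3 Nlrp3KO_STZ libraries, with 18288 to 19009 features above 0 and 13148 to 13770 at 1 TPM or more. Relative depth, with Ctrl replicate 1 as 1, ranged from 0.877 in WT_STZ replicate 1 to 1.47 in Nlrp3KO_STZ replicate 2. Ptprc, which encodes CD45, was at 160 ± 12.9 TPM in Ctrl, 154 ± 24.6 in WT_STZ and 173 ± 20.5 in Nlrp3KO_STZ (SD, n = 3). Correlations across genes of log2 values were 0.960 to 0.982 between libraries of the same group and 0.956 to 0.977 between groups, so group differences were small beside the overall profile. The first 2 principal components held 21.9% and 19.9% of the variance. The first spread libraries within groups, Ctrl replicates 1, 2 and 3 at -23.9, -0.94 and 31.2 and those of Nlrp3KO_STZ at -37.6, -15.5 and 9.91. On the second component the WT_STZ libraries lay between -27.6 and -19.5 and the others at 0.146 or above.

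Nlrp3 (chromosome 11, 59541569 to 59566955, mm10) was listed at 0 in the 3 Nlrp3KO_STZ libraries. It was at 24.4, 12.9 and 16.9 TPM in the Ctrl libraries and at 27.9, 29.5 and 29.3 TPM in the WT_STZ libraries. All WT_STZ libraries lay above all Ctrl libraries, an Nlrp3 difference of 0.69 ± 0.20 in log2 (SE) that did not pass (limma adjusted p = 0.147), with an exact permutation p of 0.1, the smallest that 3 against 3 allow. Leaving out Ctrl replicate 1 brought that difference to 0.92 and past the threshold (limma adjusted p = 0.0225). It did not pass when any other Ctrl or WT_STZ library was left out (limma adjusted p from 0.263 to 0.372), and was 0.49 without Ctrl replicate 2. Both falls to 0 passed (limma adjusted p = 2.38e-05 against WT_STZ and 9.05e-05 against Ctrl).

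**Figure D1:**
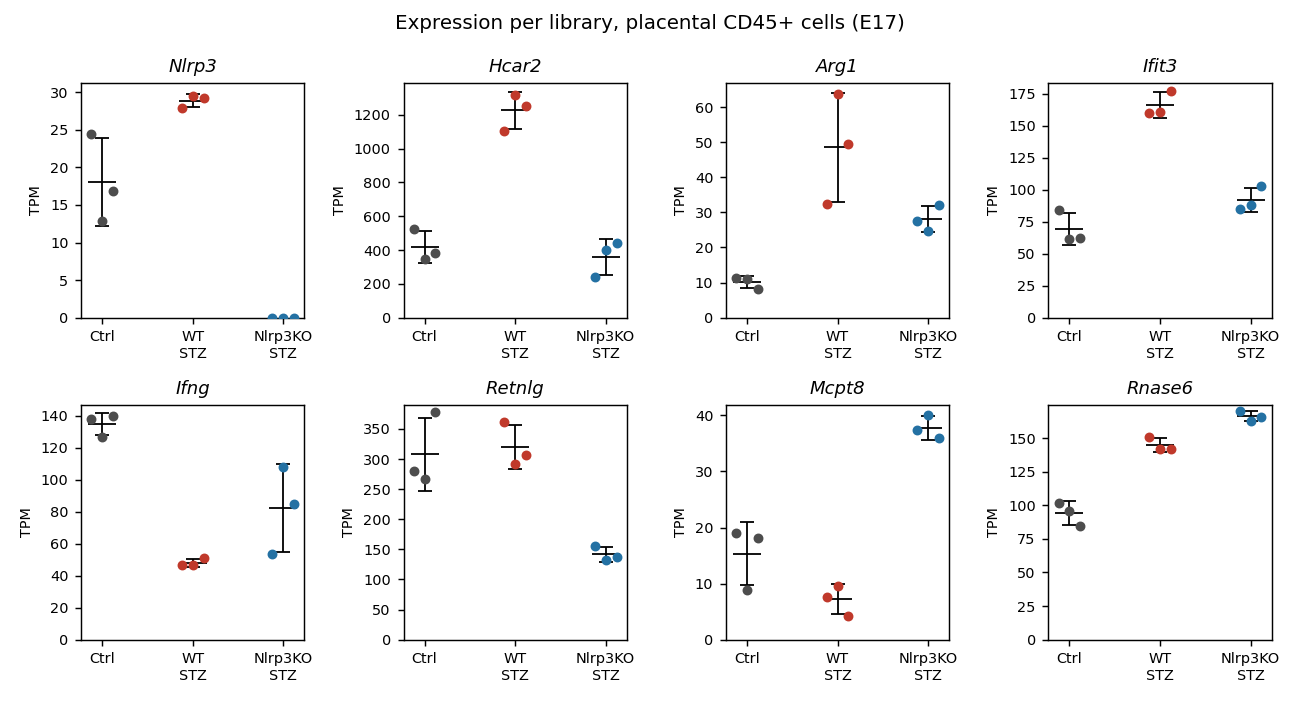
TPM (vertical axes, from 0) of 8 genes in each library of the 3 groups; points are single libraries, and the long tick and bars are the mean ± SD over 3 libraries, left out where all values are 0. Nlrp3 lay at 0 in the 3 Nlrp3KO_STZ libraries, Hcar2 and Ifit3 were highest in WT_STZ, and Mcpt8 lay between 35.9 and 40.1 TPM in Nlrp3KO_STZ, above the other groups.

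Diabetic pregnancy was first compared with normal pregnancy in wild-type cells. The arginase gene Arg1, the metabolite receptor gene Hcar2 and 7 of 30 fixed interferon-stimulated genes rose, while Ifng, Cd40lg and the chaperone gene Hsp90ab1 fell. In all, 67 of 14160 genes changed (limma, Benjamini-Hochberg adjusted p below 0.05), 51 higher and 16 lower, of which 16 were predicted genes or small RNAs. Hcar2, a receptor for niacin and β-hydroxybutyrate (chromosome 5, 123863570 to 123865516), rose from 418 ± 96.1 to 1226 ± 109 TPM (log2 1.57 ± 0.23 SE, adjusted p = 0.0360). Arg1 (chromosome 10, 24915207 to 24927470), which splits arginine into ornithine and urea, rose from 10.2 ± 1.79 to 48.5 ± 15.6 TPM (log2 2.11 ± 0.24, adjusted p = 0.0223). The other large rises were Fam71f2 (log2 2.17), the small GTPase gene Rab15 (1.68), the tight junction gene Cldn1 (1.62), the Rho-family GTPase gene Rhov (1.46), Upp1, a uridine phosphorylase (1.46), and Ifi44 (1.41), with adjusted p between 0.0360 and 0.0438.

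Ifng (chromosome 10, 118441046 to 118445894), which encodes interferon-γ, fell from 135 ± 7.06 to 48.1 ± 2.66 TPM (log2 -1.47 ± 0.21, adjusted p = 0.0360). Cd40lg, the ligand of CD40 on activated T cells, fell from 101 ± 11.2 to 51.5 ± 3.40 TPM (log2 -0.96 ± 0.11, adjusted p = 0.0223). The fixed T cell markers, described below, had a median of -0.57. The falls of Ifng and Cd40lg were not separated from a smaller share of T cells. Got1, a cytosolic aspartate aminotransferase, fell from 145 ± 33.9 to 56.0 ± 9.31 TPM. The remaining named falls were Arc (log2 -1.74), Rasl11b (-1.59), Bambi-ps1 (-1.10), Gramd3 (-0.94) and the pseudokinase gene Trib2 (-0.92), with adjusted p between 0.0311 and 0.0471. Hsp90ab1, chosen after its values were seen, fell from 3131 ± 208 to 1668 ± 96.3 TPM (adjusted p = 0.0360).

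Of the 33 fixed lists, 12 were called by camera in this comparison, 7 higher and 5 lower. None of the 12 was called with an estimated correlation, where their adjusted p ran from 0.220 to 0.803, and fry called 9 lists, 6 of them among the 12. The other lists called by fry were mast cell, basophil and eosinophil (fry adjusted p = 0.0127, camera 0.189), stem and progenitor (0.0222, camera 0.0520) and endothelial markers (0.0369, camera 0.157). All 30 interferon-stimulated genes had positive fold changes (median 0.65, camera adjusted p = 1.79e-21, adjusted p = 0.220 with an estimated correlation). Of these, 7 rose when adjusted over all genes and 26 when adjusted over the list alone. Counts adjusted over a list alone are not corrected for the 33 lists. Lists without a camera call had such genes too, with 6 inflammatory cytokines higher and 1 lower, and 3 chemokines higher. Ifit3 rose from 69.3 ± 12.8 to 166 ± 9.80 TPM, though its reads are uncertain because Ifit3b is a near copy. Ifit1 rose from 100 ± 15.8 to 217 ± 33.1 TPM, Ifit2 from 51.6 ± 7.36 to 108 ± 10.9 TPM, and Usp18, a protease that removes ISG15, from 233 ± 18.7 to 425 ± 18.1 TPM.

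Inflammasome and pyroptosis genes were positive for 20 of 22 members (median 0.39, camera adjusted p = 2.46e-06, adjusted p = 0.220 with an estimated correlation). None passed over all genes and 4 rose when adjusted over the list alone. Il1b was at 758 ± 324 TPM in Ctrl and 1337 ± 106 in WT_STZ, and Casp1 at 183 ± 25.5 and 238 ± 4.54 TPM. NRF2 antioxidant genes were positive for 21 of 23 (median 0.32, camera adjusted p = 8.71e-08, adjusted p = 0.220 with an estimated correlation), none passed over all genes, and 11 rose when adjusted over the list alone. Taldo1 of the pentose phosphate pathway was at 974 ± 37.4 and 1257 ± 30.3 TPM, and Nqo1 at 2.37 ± 0.49 and 5.03 ± 0.74 TPM. Smaller shifts up were called for AGE-RAGE axis and alarmin genes (median 0.19, camera adjusted p = 0.00557, adjusted p = 0.223 with an estimated correlation) and for glycolysis (median 0.13, camera adjusted p = 0.0152, adjusted p = 0.439 with an estimated correlation). Tlr4, a receptor of alarmins, was at 15.6 ± 2.67 TPM in Ctrl and 29.0 ± 3.05 in WT_STZ (adjusted p = 0.0613). The glycolysis call was lost without Ctrl replicate 1 (adjusted p = 0.0965) or Ctrl replicate 2 (adjusted p = 0.0822), and the glycolysis median was 0.08 without WT_STZ replicate 1.

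Cell type markers moved as well. T cell markers were negative for 20 of 20 members (median -0.57, camera adjusted p = 1.40e-10, adjusted p = 0.244 with an estimated correlation), with none past the threshold over all genes and 8 lower when adjusted over the list alone. Cd4 was at 44.7 ± 7.78 TPM in Ctrl and 26.7 ± 4.45 in WT_STZ, and the T cell kinase gene Itk at 97.3 ± 25.2 and 50.1 ± 8.81 TPM. Monocyte markers were called higher (median 0.30, camera adjusted p = 8.61e-05, adjusted p = 0.220 with an estimated correlation), with 1 of 18 passing over all genes. That gene, Ly6c2, rose from 550 ± 34.7 to 881 ± 28.0 TPM, and Ccr2 was at 131 ± 29.9 and 197 ± 3.14 TPM. Neutrophil markers were called higher (median 0.37, camera adjusted p = 0.00228, adjusted p = 0.223 with an estimated correlation), with 0 of 22 passing alone.

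The immediate-early and heat-shock list was called lower (median -0.27, camera adjusted p = 0.00103, adjusted p = 0.803 with an estimated correlation), with 8 of 26 members lower when adjusted over the list alone. Hsp90aa1 was at 1268 ± 58.5 TPM in Ctrl and 691 ± 70.4 in WT_STZ, and Hspa8 at 5909 ± 523 and 3905 ± 297 TPM (adjusted p = 0.0949). That call was lost without WT_STZ replicate 1 (median -0.13, adjusted p = 0.475) and with library weights (0.0535). Ribosomal protein genes were negative for 32 of 32 members by a small amount (median -0.19, camera adjusted p = 5.57e-08, adjusted p = 0.601 with an estimated correlation). The size rested on single Ctrl libraries, with a ribosomal median of -0.32 without Ctrl replicate 1 and -0.10 without Ctrl replicate 2. Rplp1 was at 404.6 TPM in Ctrl replicate 1, 613.4 and 612 TPM in the other Ctrl libraries and 394.2 to 419 TPM in WT_STZ. Cholesterol synthesis (median -0.14, camera adjusted p = 0.00897, adjusted p = 0.220 with an estimated correlation) and trophoblast markers (median -0.69, camera adjusted p = 0.00536, adjusted p = 0.361 with an estimated correlation) were also called lower. With no filter on low values the trophoblast median was -0.07 and its call was lost (adjusted p = 0.241). The cholesterol call was lost without Ctrl replicate 3 (adjusted p = 0.0739) or WT_STZ replicate 1 (adjusted p = 0.0504), and the trophoblast call without Ctrl replicate 1 (median -0.34, adjusted p = 0.0945) or WT_STZ replicate 1 (adjusted p = 0.115), while without Ctrl replicate 3 the trophoblast median was -1.08.

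With 1 library left out, which also lowers the residual degrees of freedom, the number of genes called changed widely. It was 0 without Ctrl replicate 2, Ctrl replicate 3, WT_STZ replicate 2, WT_STZ replicate 3 or Nlrp3KO_STZ replicate 2 (limma, with 1699, 1620, 1738, 1534 and 2034 genes at an unadjusted p below 0.05), 2 without WT_STZ replicate 1 and 17 without Nlrp3KO_STZ replicate 3, but 450 without Ctrl replicate 1 and 144 without Nlrp3KO_STZ replicate 1. With all 9 libraries 2145 genes had an unadjusted p below 0.05 (limma), against 319 to 1474 in the other splits of these 6 libraries into 3 and 3. This contrast cannot exclude chance. There are only 10 splits, and mixed splits carry any group difference in their spread. The ranges of the groups were apart for 19.4% of genes where chance gives 10% on average. Genes are correlated over libraries, and how far that share varies by chance was not measured.

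**Figure D2:**
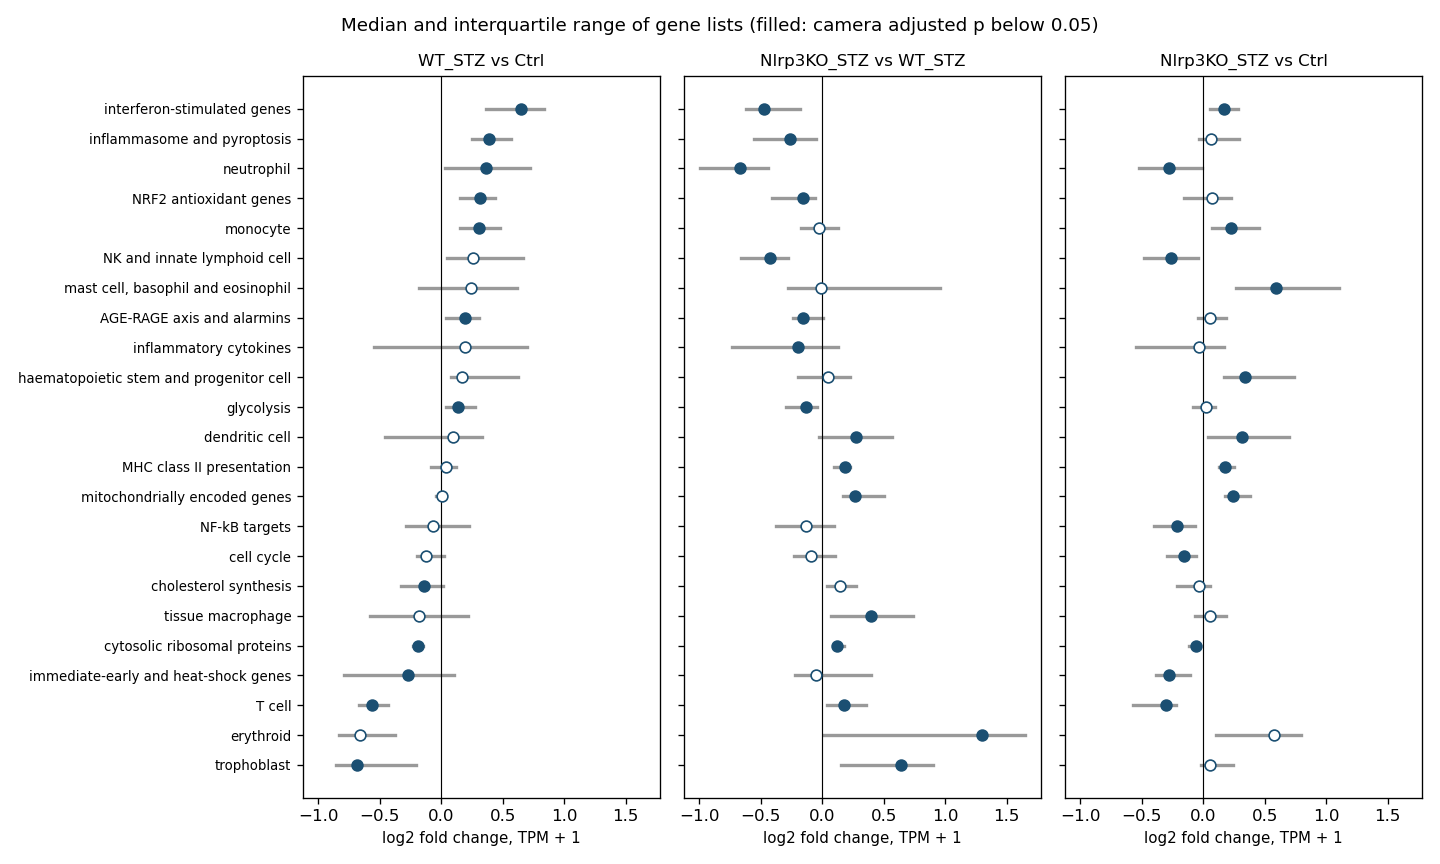
Median log2 fold change of TPM + 1 (horizontal axes, points) and interquartile range over members (bars) for the 23 gene lists called in at least 1 comparison, with 1 panel per comparison; filled points have a camera adjusted p below 0.05 at a preset correlation. Interferon-stimulated genes had a median of 0.65 in WT_STZ vs Ctrl and -0.48 in Nlrp3KO_STZ vs WT_STZ.

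The next comparison asked what differed between the diabetic pregnancies when Nlrp3 was lacking. Mcpt8, Prss34, Fcer1a and Gata2, 4 of 16 fixed mast cell, basophil and eosinophil markers, were higher in Nlrp3KO_STZ than in WT_STZ, while Hcar2, 3 of 22 neutrophil markers and 2 of 30 interferon-stimulated genes were lower. In all, 70 of 14160 genes changed (limma), 12 higher and 58 lower, of which 21 were predicted genes or small RNAs. The balance was 15 higher and 18 lower without Nlrp3KO_STZ replicate 1, and 7 higher and 11 lower with no filter on low values. Mcpt8, a basophil granule protease (chromosome 14, 56082163 to 56085499), rose from 7.17 ± 2.68 to 37.8 ± 2.13 TPM (log2 2.30 ± 0.31 SE, adjusted p = 0.0329). Fcer1a, a chain of the IgE receptor, rose from 1.43 ± 0.67 to 9.53 ± 1.51 TPM (adjusted p = 0.0220), the protease gene Prss34 from 17.5 ± 5.56 to 62.0 ± 4.47 TPM (adjusted p = 0.0464), and Gata2, a transcription factor of mast cells, basophils and progenitors, from 10.9 ± 0.64 to 22.0 ± 4.09 TPM (adjusted p = 0.0455). Mpeg1, which encodes perforin-2, rose from 43.1 ± 5.28 to 165 ± 41.3 TPM. ND3, a mitochondrial complex I gene, rose by 1.18 in log2, and Snrpf, a core splicing protein, by 0.68.

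Among the 58 lower genes, Nlrp3 was listed at 0. Hcar2 fell from 1226 ± 109 to 360 ± 105 TPM (log2 -1.81 ± 0.23, adjusted p = 0.0329), and Rhov from 44.9 ± 4.29 to 11.2 ± 2.72 TPM (log2 -1.93 ± 0.22, adjusted p = 0.0264). The other large falls were Fam71f2 (log2 -2.14), AW011738 (-2.08), Ifit1bl2 (-1.84), the cystine transporter gene Slc7a11 (-1.77) and Upp1 (-1.77), with adjusted p between 0.0329 and 0.0480. 2610507I01Rik, a predicted gene named after its values were seen, was at 26.4 ± 4.06 TPM in WT_STZ and at 0.2, 0.1 and 0.1 TPM in Nlrp3KO_STZ, and lies 0.344 Mb from Nlrp3 on chromosome 11 (59197793 to 59202431).

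By camera 16 lists were called, 8 higher and 8 lower. None was called with an estimated correlation, where adjusted p ran from 0.0559 to 0.677, and fry called 2 lists, neutrophil markers (fry adjusted p = 0.00427) and mast cell, basophil and eosinophil markers (0.0143), of which camera called the former. Neutrophil markers were negative for 20 of 22 members (median -0.67, camera adjusted p = 1.16e-12, adjusted p = 0.0559 with an estimated correlation), with 3 lower over all genes and 14 when adjusted over the list alone. Retnlg (chromosome 16, 48872608 to 48874498) fell from 320 ± 36.9 to 142 ± 12.7 TPM, Mrgpra2b from 16.1 ± 1.56 to 5.33 ± 1.45 TPM, and S100a9, a subunit of the alarmin calprotectin, from 852 ± 58.0 to 492 ± 44.3 TPM. Interferon-stimulated genes were negative for 29 of 30 (median -0.48, camera adjusted p = 8.13e-15, adjusted p = 0.324 with an estimated correlation), with 2 lower over all genes and 18 when adjusted over the list alone. Ifit3 fell from 166 ± 9.80 to 92.1 ± 9.43 TPM, with the same uncertainty from its near copy, and Ifit1 from 217 ± 33.1 to 118 ± 6.81 TPM, while Isg15 was at 387 ± 72.2 and 172 ± 16.8 TPM (adjusted p = 0.0645).

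NK and innate lymphoid markers were called lower (median -0.43, camera adjusted p = 9.09e-08, adjusted p = 0.324 with an estimated correlation), and Eomes, a transcription factor of NK cells, fell from 17.4 ± 2.17 to 9.37 ± 0.86 TPM. NRF2 antioxidant genes were called lower (median -0.16, camera adjusted p = 4.17e-06, adjusted p = 0.324 with an estimated correlation), with falls of Slc7a11 and of Nqo1, from 5.03 ± 0.74 to 1.57 ± 0.15 TPM. Inflammasome and pyroptosis genes were negative for 17 of 22 (median -0.26, camera adjusted p = 0.000314, adjusted p = 0.324 with an estimated correlation). None of them passed over all genes, with Il1b at 1337 ± 106 TPM in WT_STZ and 643 ± 96.0 in Nlrp3KO_STZ (adjusted p = 0.138). Of the inflammatory cytokines, Il1rn, the interleukin-1 receptor antagonist (chromosome 2, 24336860 to 24351491), fell from 123 ± 19.7 to 47.4 ± 3.89 TPM (adjusted p = 0.0329), with the list called at camera adjusted p = 0.0349 and adjusted p = 0.662 with an estimated correlation. Glycolysis (median -0.14, camera adjusted p = 0.00315) and AGE-RAGE axis and alarmin genes (median -0.15, camera adjusted p = 0.0246) were called lower, each at adjusted p = 0.362 with an estimated correlation. With library weights the cytokine (adjusted p = 0.127) and AGE-RAGE (0.0566) calls were lost. Medians also rested on single libraries: without WT_STZ replicate 1 the NK median was -0.25, and without Nlrp3KO_STZ replicate 1 the NRF2 median was -0.10 and the AGE-RAGE median -0.06. The cytokine median, -0.20 with all libraries, was -0.39 and -0.03 without WT_STZ replicates 1 and 3, and -0.08, -0.42 and -0.36 without Nlrp3KO_STZ replicates 1, 2 and 3.

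Lists called higher were mitochondrially encoded genes (median 0.26, camera adjusted p = 0.000239), ribosomal proteins (0.12, 0.00108), dendritic cell markers (0.27, 0.00750), MHC class II presentation (0.18, 0.00757), trophoblast (0.64, 0.0135), tissue macrophage (0.39, 0.0246), T cell (0.17, 0.0320) and erythroid markers (1.30, 0.0491), in each of which 0 members passed over all genes apart from ND3. Their adjusted p ran from 0.324 to 0.677 with an estimated correlation. With no filter on low values the erythroid median was 0.09 (adjusted p = 0.269) and the trophoblast median 0.16 (0.0649), and both calls were lost. The erythroid call was also lost with a pseudocount of 5 (median 0.67, 0.0508) and without small RNA loci (0.65, 0.0871). At a mean of 5 TPM or more, the tissue macrophage median was 0.12 (0.322) and the dendritic cell median 0.09 (0.281), and both calls were lost. The T cell median was 0.32 without WT_STZ replicate 1 and 0.11 without Nlrp3KO_STZ replicate 1, where the MHC class II median was 0.12. C1qa, a complement gene of macrophages, was at 56.6 ± 12.1 TPM in WT_STZ and 119 ± 11.7 in Nlrp3KO_STZ, and Hbb-bs, a globin gene, at 224 ± 38.6 and 743 ± 232 TPM. Mast cell, basophil and eosinophil markers had 4 of 16 members higher over all genes, with 9 members negative, a median of -0.01 and a mean of 0.34. Camera did not call this list (adjusted p = 0.0648, and 0.324 with an estimated correlation), while fry did (0.0143).

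Here too the count changed widely with 1 library left out. It was 2 without Nlrp3KO_STZ replicate 2, 3 without WT_STZ replicate 3, 5 without WT_STZ replicate 2, 6 without WT_STZ replicate 1, 8 without Nlrp3KO_STZ replicate 3, 33 without Nlrp3KO_STZ replicate 1, 39 without Ctrl replicate 2 and 165 without Ctrl replicate 1. Without WT_STZ replicate 1 the calls of MHC class II, tissue macrophage and trophoblast genes (adjusted p = 0.187 each) and of erythroid genes (0.131) were lost. Without WT_STZ replicate 2 those of cytokine and T cell genes (0.112 each), AGE-RAGE (0.0841) and erythroid genes (0.0944) were lost, and without WT_STZ replicate 3 those of cytokine (0.0933), T cell (0.119) and erythroid genes (0.0568). Without Nlrp3KO_STZ replicate 1 the calls of cytokine (0.889), AGE-RAGE (0.245) and T cell genes (0.270) were lost, without replicate 2 those of tissue macrophage (0.0970), erythroid (0.209) and trophoblast genes (0.103), and without replicate 3 that of tissue macrophage genes (0.0745). Without Ctrl replicate 3, which belongs to neither group here, 14 of the 16 lists were called.

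Nlrp3KO_STZ and Ctrl differed in genotype and in diabetes together. Of 14160 genes 3 passed (limma; 1805 at an unadjusted p below 0.05). Rnase6, an antimicrobial ribonuclease (chromosome 14, 51123908 to 51132187), rose from 94.1 ± 8.96 to 166 ± 3.96 TPM (log2 0.82 ± 0.09, adjusted p = 0.0332), and Nlrp3 and 2610507I01Rik were lower. Without Ctrl replicate 1 the count was 25, and without Nlrp3KO_STZ replicate 1 it was 8. The rise of Rnase6, Nlrp3KO_STZ vs Ctrl, passed without Ctrl replicate 1 (adjusted p = 0.0199) but not without Ctrl replicate 2 (0.105), Ctrl replicate 3 (0.0556) or Nlrp3KO_STZ replicates 1 (0.0585), 2 (0.15) or 3 (0.170), nor without any 1 of the WT_STZ libraries, where 0 genes were called higher (limma, with 1768, 1623 and 1577 genes at an unadjusted p below 0.05 without replicates 1, 2 and 3).

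Of 14 lists called by camera, 7 were higher and 7 lower, none with an estimated correlation, and 5 by fry. Mast cell, basophil and eosinophil markers had a median of 0.59 (camera adjusted p = 1.76e-05, adjusted p = 0.0643 with an estimated correlation), with none past the threshold over all genes and 8 of 16 higher when adjusted over the list alone. Over the alternatives that median ran from 0.24 to 1.05, and the median of stem and progenitor markers from 0.09 to 0.41. Both lists kept their camera calls at the preset correlation. The protease gene Cpa3, of the mast cell, basophil and eosinophil list, was at 10.5 ± 6.57 TPM in Ctrl and 45.7 ± 3.41 in Nlrp3KO_STZ (limma adjusted p = 0.0803). Monocyte (median 0.23), dendritic cell (0.31), MHC class II (0.18), interferon-stimulated (0.17), stem and progenitor (0.34) and mitochondrially encoded genes (0.24) were called higher, with adjusted p from 0.187 to 0.683 with an estimated correlation. T cell (median -0.31), neutrophil (-0.28), NF-kB target (-0.21), immediate-early and heat-shock (-0.28), cell cycle (-0.16) and ribosomal protein genes (-0.06) were called lower, with adjusted p from 0.187 to 0.835 with an estimated correlation. NK and innate lymphoid markers were called lower with a median of -0.26 but a mean of 0.25 (camera adjusted p = 0.000405, adjusted p = 0.487 with an estimated correlation). Gzmb, a cytotoxic granule protease, was at 911 ± 72.6 TPM in Ctrl and 537 ± 55.3 in Nlrp3KO_STZ (adjusted p = 0.0506), and Cd209a at 335 ± 53.4 and 764 ± 67.1 TPM (adjusted p = 0.0502). The dendritic cell call was lost at a mean of 5 TPM or more (median 0.16, adjusted p = 0.160). With library weights the calls of NF-kB target (0.154), mitochondrially encoded (0.0925) and immediate-early and heat-shock genes (0.0638) were lost, and with quantile scaling that of ribosomal proteins (0.165). The ribosomal call was lost without Ctrl replicate 2, where the median was 0.03 (adjusted p = 0.924), without Ctrl replicate 3 (median -0.02, 0.438), and without Nlrp3KO_STZ replicates 2 (0.0808) or 3 (median -0.03, 0.134), while its median was -0.20 without Ctrl replicate 1 and -0.11 without Nlrp3KO_STZ replicate 1. The mitochondrial call was lost without Ctrl replicate 3 (median 0.05, adjusted p = 0.399), and the immediate-early and heat-shock call without Nlrp3KO_STZ replicate 1 (median -0.09, adjusted p = 0.245).

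Other medians of this comparison also moved by over 1.5 times when 1 library was left out, with their camera calls kept. Without Ctrl replicate 1 the medians were -0.13 for NF-kB targets, -0.15 for NK, 0.29 for interferon-stimulated and 0.37 for monocyte genes. Without Ctrl replicate 2 they were -0.33 for NF-kB targets and 0.10 for interferon-stimulated genes, and without Ctrl replicate 3 -0.42 for NK and 0.11 for interferon-stimulated genes. Without Nlrp3KO_STZ replicate 1 the MHC class II median was 0.09, and without Nlrp3KO_STZ replicate 3 the medians were -0.32 for NF-kB targets, -0.43 for neutrophil and 0.11 for interferon-stimulated genes.

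The WT_STZ libraries enter both the comparison with Ctrl and that with Nlrp3KO_STZ, so their chance deviations appear in both with opposite signs. Of the 51 genes called higher in WT_STZ, 17 were called lower in Nlrp3KO_STZ vs WT_STZ, among them Hcar2, Rhov, Upp1, Fam71f2, Ifit1 and Ifit3. The 17 also included predicted genes and small RNAs, such as Gm26535 and Mir6945. Of the 16 called lower in WT_STZ, 2 were called higher in Nlrp3KO_STZ vs WT_STZ, Snrpf and the predicted gene Gm38670. No gene was called in the same direction in both. Lists of independent genes would share 0.209 and 0.0136 genes, and simulated unchanged groups shared 1.59 on average, with a maximum of 159. The fold changes correlated at r = -0.60 over 14160 genes, which are not independent replicates, where unchanged groups sharing the WT_STZ libraries gave -0.47 on average (range -0.96 to 0.49). The observed value lay within that range, and the signs were opposite for 69.1% of genes against a simulated 66.7%. The covariance was -0.0923 against a simulated -0.0455. Fold changes of both diabetic groups against Ctrl correlated at 0.45 (simulated 0.48, covariance 0.0616 against 0.0485), and 1 gene, Rnase6, was called in both. Groups of 3 cannot be split into parts of 2 libraries each, so part of both overlaps may come from the shared libraries. With no group lacking Nlrp3 in a normal pregnancy, a genotype difference independent of diabetes could not be told apart from a reversal.

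Lists without a camera call in any comparison had lowest camera adjusted p of 0.0539 for B and plasma cells, 0.0729 for nuclear-encoded oxidative phosphorylation, 0.157 for endothelial, 0.261 for stromal and decidual, 0.266 for chemokine, 0.349 for megakaryocyte and platelet, 0.388 for unfolded protein response, 0.584 for hypoxia, 0.664 for chromatin regulator and 0.910 for yolk sac endoderm and hepatocyte genes.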

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

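Under all alternatives run, none of the 46 calls of named genes reversed in direction. This was largely fixed in advance, since all genes called (67, 70 and 3) had no overlap between the libraries of the 2 groups. Leaving out a library or changing the pseudocount cannot turn the sign of such a gene, so the absence of reversals says little about stability. Of 42 list calls 1 reversed, the ribosomal proteins in Nlrp3KO_STZ vs Ctrl, with a median of 0.0274 without Ctrl replicate 2 and -0.1983 without Ctrl replicate 1. When each library of the groups compared was left out in turn, 2 of the 46 gene calls were kept throughout, both of them Nlrp3, and 28 of the 42 list calls; single genes were not followed when a library of the remaining group was left out. Most gene calls lay close to the threshold, and the cause of the changes below was not tested beyond the construction of each alternative (fewer libraries, more genes tested). For WT_STZ vs Ctrl the 67 genes became 7 with no filter on low values, 35 with only the groups compared, 15 with no trend and 781 with library weights, and 0 to 450 with a library left out. For Nlrp3KO_STZ vs WT_STZ the 70 became 27 with a pseudocount of 0.1, 18 with no filter, 25 with median-of-ratios factors, 114 with only the groups compared, 37 with no trend and 367 with library weights, and 2 to 165 with a library left out. For Nlrp3KO_STZ vs Ctrl the 3 became 19 and 8 with pseudocounts of 0.1 and 5, 15 at a mean TPM of 5 or more, 16 with quantile scaling, 7 without erythroid and mitochondrial genes, 145 with library weights, 18 without small RNA loci (chosen after seeing the data), and 2 to 25 with a library left out. In that comparison 1 of 3 calls was higher, against 10 of 19 and 6 of 8 with pseudocounts of 0.1 and 5, 2 of 4 with no filter, 7 of 15 at a mean TPM of 5 or more, 6 of 16 with quantile scaling, 5 of 7 without erythroid and mitochondrial genes, 105 of 145 with library weights, 9 of 18 without small RNA loci, 17 of 25 without Ctrl replicate 1 and 5 of 8 without Nlrp3KO_STZ replicate 1; it was 0 of 2 with only the groups compared, with no trend, and without Ctrl replicate 2, WT_STZ replicates 1 or 3 or Nlrp3KO_STZ replicate 3, and 0 of 3 without WT_STZ replicate 2 or Nlrp3KO_STZ replicate 2. In Nlrp3KO_STZ vs WT_STZ 12 of 70 were higher, against 7 of 18 with no filter, 108 of 367 with library weights, 15 of 33 without Nlrp3KO_STZ replicate 1, 2 of 6 and 1 of 3 without WT_STZ replicates 1 and 3, and 0 of 2 without Nlrp3KO_STZ replicate 2. In WT_STZ vs Ctrl 51 of 67 were higher, against 13 of 15 with no trend, 512 of 781 with library weights, 14 of 22 with the replicate number as a block, 2 of 2 without WT_STZ replicate 1 and 15 of 17 without Nlrp3KO_STZ replicate 3. List calls also ended with processing: with no filter on low values, trophoblast in WT_STZ vs Ctrl (-0.07) and in Nlrp3KO_STZ vs WT_STZ (0.16) and erythroid in the latter (0.09); at a mean TPM of 5 or more, tissue macrophage (0.12) and dendritic cell (0.09) in the latter and dendritic cell in Nlrp3KO_STZ vs Ctrl (0.16). Quantile scaling ended the ribosomal call in Nlrp3KO_STZ vs Ctrl (-0.05), and a pseudocount of 5 (0.67) or TPM without small RNA loci (0.65) the erythroid call. Library weights ended 6 calls: immediate-early and heat-shock genes in WT_STZ vs Ctrl (-0.12) and Nlrp3KO_STZ vs Ctrl (-0.16), cytokines (-0.09) and AGE-RAGE (-0.12) in Nlrp3KO_STZ vs WT_STZ, and NF-kB targets (-0.07) and mitochondrial genes (0.14) in Nlrp3KO_STZ vs Ctrl. The weights were lowest for Ctrl replicate 1 (0.484) and Nlrp3KO_STZ replicate 1 (0.510) and brought the Nlrp3 difference of WT_STZ vs Ctrl to 0.88, past the threshold; over libraries left out it was 0.49 to 0.92. With an estimated correlation 0 lists were called in each comparison, and fry called 2 in Nlrp3KO_STZ vs WT_STZ and 5 in Nlrp3KO_STZ vs Ctrl. The replicate numbers showed no pairing common to the 3 groups. Deviations of same-numbered libraries correlated at -0.233 to 0.289, over 0.1 in 2 of 9 pairs, and those of different-numbered libraries at -0.203 to 0.159. Same-numbered pairs of Ctrl and Nlrp3KO_STZ were all positive (0.143, 0.049 and 0.289). Those of Ctrl and WT_STZ were all negative (-0.098, -0.110 and -0.233), and those of WT_STZ and Nlrp3KO_STZ went both ways. A pairing of Ctrl with Nlrp3KO_STZ libraries is therefore not excluded, though no label names one. With the replicate number as a block the counts were 22, 8 and 3. Depth limits genes near 1 TPM, which rest on 7.93 to 13.25 reads per kb.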

Other observations

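The test of heat-shock against immediate-early genes was chosen after results had been seen, and the other tests were set before. Of the 58 genes called lower in Nlrp3KO_STZ than in WT_STZ (limma), 6 outside the rule are given here, chosen after their values were seen; no list or test ties them together. Fpr1 and Fpr2, receptors of formylated peptides, fell from 69.7 ± 6.12 to 29.2 ± 6.01 TPM (adjusted p = 0.0329) and from 63.3 ± 10.1 to 29.7 ± 1.22 TPM (adjusted p = 0.0329). Clec4d, a C-type lectin receptor, fell from 92.2 ± 15.6 to 35.3 ± 8.59 TPM (adjusted p = 0.0481), Lrg1 from 104 ± 18.0 to 34.8 ± 5.71 TPM (adjusted p = 0.0370), Arg2 from 181 ± 21.3 to 62.3 ± 3.50 TPM (adjusted p = 0.0455) and the lipolysis inhibitor G0s2 from 1144 ± 205 to 380 ± 9.26 TPM (adjusted p = 0.0268). In WT_STZ vs Ctrl these 6 had positive fold changes that did not pass, from 0.55 for Lrg1 to 1.08 for Arg2. Neutrophil markers moved the same way as a list, with medians of 0.37 in WT_STZ vs Ctrl and -0.67 in Nlrp3KO_STZ vs WT_STZ. The changes of these 6 genes were not separated from a change in neutrophil share. Arg1, the other arginase, was at 28.1 ± 3.77 TPM in Nlrp3KO_STZ, between Ctrl and WT_STZ. All of these calls were made at 3 libraries per group and most gene calls were lost when a library was left out.

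The mast cell, basophil and eosinophil list was not called by camera in Nlrp3KO_STZ vs WT_STZ (adjusted p = 0.0648) but was by fry (adjusted p = 0.0143), and its members were not tested against each other. Cpa3, a member of the list, was at 10.5 ± 6.57 TPM in Ctrl. It was at 35.4, 75.5 and 36.6 TPM in the WT_STZ libraries and at 47.2, 48.1 and 41.8 in Nlrp3KO_STZ, with limma adjusted p of 0.0566 and 0.0803 against Ctrl. The basophil protease gene Mcpt8 was at 19, 8.9 and 18.2 TPM in Ctrl, 7.6, 9.6 and 4.3 in WT_STZ and 37.4, 40.1 and 35.9 in Nlrp3KO_STZ. Transcripts of the Y chromosome were low, with Ddx3y at 0.4 to 1.8 TPM over the 9 libraries and its X-linked partner Ddx3x at 89.1 to 156.9 TPM, and Xist was at 5.5 to 10.5 TPM. The labels do not say whether the sorted cells were maternal or fetal.

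All 30 interferon-stimulated genes had positive fold changes in WT_STZ vs Ctrl, 7 of them passing, with a median of 0.65 in log2 (95% bootstrap interval over genes 0.54 to 0.75), although Ifng itself was lower; the list's call was lost with an estimated correlation (adjusted p = 0.220). More monocytes were weighed first: monocyte markers had a median of 0.30, a difference of 0.35 (0.15 to 0.51). By the rule set before, this goes against a larger monocyte share as the whole cause, but it does not settle the question. The 18 markers did not move as one, with 14 positive and 4 negative, and Ly6c2, which passed, rose by 0.65 to 0.73 in log2 over the alternatives. The draws were over genes, not libraries, and ignore correlation between members. Scaling of TPM to a fixed total was weighed next, and with median-of-ratios factors the interferon median was 0.64 (0.53 to 0.73). Neutrophil markers, called higher by camera (median 0.37), and T cell markers, called lower (-0.57), were not weighed against the interferon rise. A response to diabetic pregnancy in several cell types may remain. No table separates it from a change in cell types, inside or outside the fixed lists, or from other differences between the samples. No other split of the 6 libraries gave more than 2 genes against the real 67, and 10 splits are too few for a share under 0.05: 1 of 10 gave as many.

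The 58 genes called lower in Nlrp3KO_STZ than in WT_STZ included 3 of the 22 fixed neutrophil markers. Neutrophil markers had a median of -0.67 and the 58 genes called lower -1.36, a difference of 0.69 (0.26 to 1.09), but the 58 were picked for large falls, which biases their median downward, so this comparison decides nothing and a smaller neutrophil share stays open. If a segment of another strain carried along with the deleted gene caused most of the falls, most of the lower genes would lie near Nlrp3. Of the 58, 5.17% lay within 20 Mb of it (3 genes: Nlrp3, 2610507I01Rik and Mapk7), where 2.98% of all tested genes lie. Without Nlrp3 itself 2 of 57 did (Fisher's exact p = 0.687). A window this wide cannot detect a short segment that changes a few genes, so the test does not count against one. 2610507I01Rik, 0.344 Mb away, and Mapk7, 1.95 Mb away, may still be such passenger genes. Of 10 splits 1 gave as many as 70 genes and the highest other gave 1, and for Nlrp3KO_STZ vs Ctrl 1 of 10 gave as many as 3 and the highest other gave 1, again too few splits for a share under 0.05.

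The 8 heat-shock members of the fixed list had a median of -0.94 (-1.25 to -0.86) in WT_STZ vs Ctrl, but none of them passed (limma adjusted p from 0.0765 to 0.143), and the call of their list was lost with an estimated correlation (0.803), with library weights (0.0535) and without WT_STZ replicate 1 (0.475). In the same comparison a rise of the immediate-early members, looked for because Fos was at 0.65 ± 0.16 in log2, was not borne out: their median was -0.0924 (-0.27 to 0.22). Both medians are negative, but the immediate-early members went both ways with an interval that includes 0, so a difference in tissue handling that moves dissociation-induced genes one way is neither excluded nor borne out, and it stays open beside an effect of diabetic pregnancy, which was not tested. Hspa1a and Hspa1b are near-identical copies, and the 2 stand for uncertain shares of the same reads.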
